A study of Homo sapiens with 4 samples.

How the data were processed

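RNA from BEAS-2B cells was sequenced in 4 libraries, with 1 library in each of 4 groups: untreated control, LPS for 2 h, occludin siRNA for 24 h followed by LPS for 2 h (siOCLN+LPS), and a wild-type occludin transfection for 24 h followed by LPS for 2 h (labelled wtOCLN+LPS). Libraries were made from 1.3 µg of total RNA with a directional kit, per the labels' protocols. The control and LPS libraries carry no mention of a transfection or a mock transfection. Groups were taken from the treatment given in the labels.

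The deposited values were whole-number counts of reads for 24424 gene symbols, with no duplicate symbol and no row lacking a gene name. TopHat, Cufflinks and the genome build hg19 are named in the submitters' processing notes, without versions or roles. The counting tool, its strand setting, its treatment of reads that match several genes, and the annotation are not given in the sources used here. Genes that share reads with a near-identical copy, an overlapping gene or an antisense gene are therefore uncertain. Library totals ran from 13867494 to 17500031 counts, so that 1 count was worth 0.0571 to 0.0721 CPM (counts scaled to a library total of 1000000).

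The design fixed before the data were examined assumed FPKM values. Because the deposited unit was counts, CPM from the library totals took the place of FPKM, with all thresholds kept. Ratios were taken on the log2(CPM + 1) scale, which understates the change of genes with low counts. Genes at CPM 1 or more in either library of a comparison were tested, and a gene was counted as higher or lower when it lay at least 2-fold apart. With 1 library per group there was no replicate check, no p-value was computed, and edgeR's quasi-likelihood test could not be fitted. Each statement compares libraries, not conditions. Folds named in the text are ratios of CPM without a pseudocount, with exact 95% intervals (Clopper-Pearson on the counts of both libraries), and single CPM values have exact Poisson intervals. The kit description names no molecular identifiers, so these intervals cover counting error only and not the spread between cultures. For a gene with 0 counts in 1 library, the counts are given and no fold.

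The 34 gene lists were fixed at the same time. Of 1178 listed memberships, 1163 were found under the listed symbol or an older one. For each list with at least 5 tested members, the median log2 ratio was set against 10000 random lists of the same size, drawn from the tested genes and matched on mean expression in 20 bins. A list was said to stand apart below percentile 2.5 or above 97.5. These percentiles describe these libraries only, and genes of one list are often regulated together. The named genes followed a rule of the same date: OCLN, the 10 genes with the highest and the 10 with the lowest log2 ratio among those at CPM 5 or more in either library (small RNA genes left out), and up to 4 members with the largest absolute log2 ratio from each list described. Genes named outside this rule are marked as chosen after their values were seen.

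Also fixed beforehand were the other settings tried, namely pseudocounts of 0.1 and 5, no filter and a filter at CPM 5, thresholds of 1.5-fold and 3-fold, median ratio and upper quartile scaling, small RNA genes left out, the mean in place of the median of a list, and random lists not matched on expression. Added after seeing the data were TMM scaling, the control library in place of the LPS library as reference, removal of the trend of the log2 ratio with transcript length and GC content, the interferon list left out, and readthrough symbols left out. Transcript length and GC content came from the longest GENCODE 29 transcript of each symbol, which gave values for 21875 symbols. That annotation is on another build than hg19, so no coordinates are given. For comparisons that share the LPS library, unchanged libraries were simulated from the LPS counts in 20 draws, with a biological coefficient of variation of 0.0467, estimated from the spread between the 2 transfected libraries, and again with 0.2.

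The count and list steps were tested on simulated counts. For LPS against control, in a step of 13424 genes, 50 of 50 genes made 3-fold higher and 50 of 50 made 3-fold lower were called, none of 50 made 1.5-fold higher was called, and 0 of 13204 unchanged genes were called. For siOCLN+LPS against LPS, in a step of 13338 genes, 50 of 50 genes made 3-fold higher and 48 of 50 made 3-fold lower were called. A list of 20 genes made higher lay at percentile 100 in each simulated comparison, and 3 to 5 of 100 unchanged lists stood apart. The simulated counts varied by counting error alone. Analyses used Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 for the TMM factors.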

Results

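BEAS-2B is an immortalised line of human bronchial epithelial cells. Gene expression was measured by RNA sequencing in cells left untreated, given LPS (bacterial lipopolysaccharide, a ligand of TLR4) for 2 h, or transfected for 24 h with an siRNA against occludin or with wild-type occludin and then given LPS for 2 h. Occludin, encoded by OCLN, is a transmembrane protein of tight junctions. There was 1 library per group. Total counts were 15889736 in control, 13867494 in LPS, 17476333 in siOCLN+LPS and 17500031 in the library labelled wtOCLN+LPS, and 12887 to 13306 genes reached 1 CPM. The most abundant gene, EEF1A1 or ACTB, took 0.568% to 0.656% of a library. Across genes, which are not independent replicates, log2(CPM + 1) values had a Pearson r of 0.984 between control and LPS, 0.966 between LPS and siOCLN+LPS, and 0.995 between the transfected libraries. The transfected libraries still differed by more than sampling noise (chi-square per degree of freedom 7.12), so they were treated as separate libraries.

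OCLN, the targeted gene, was lower in both transfected libraries than in control or LPS, whose labels mention no transfection. It stood at 55.4 CPM in control (95% interval 51.8 to 59.2), 50.4 CPM in LPS (46.7 to 54.3), 21.0 CPM in siOCLN+LPS (18.9 to 23.3) and 29.7 CPM in the library labelled wtOCLN+LPS (27.2 to 32.3). LPS against control gave a fold of 0.909 (0.822 to 1.01), within counting error of 1. The siRNA library had 0.417 of the OCLN level of the LPS library (0.366 to 0.473), in the direction of its label. The library labelled wtOCLN+LPS had 0.588 of that level (0.524 to 0.660), against the direction that its label implies, so it is called by its label throughout and no direction drawn from it is a direction of raised occludin. It held 1.41 times the OCLN level of the siRNA library (1.23 to 1.62). Because OCLN lay below LPS in both transfected libraries, the fall in siOCLN+LPS cannot be put down to the siRNA alone. OCLN has a partial copy elsewhere in the genome, and reads shared with that copy could not be separated. These values did not exclude an exchange of the labels of the transfected libraries.

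**Figure D1:**
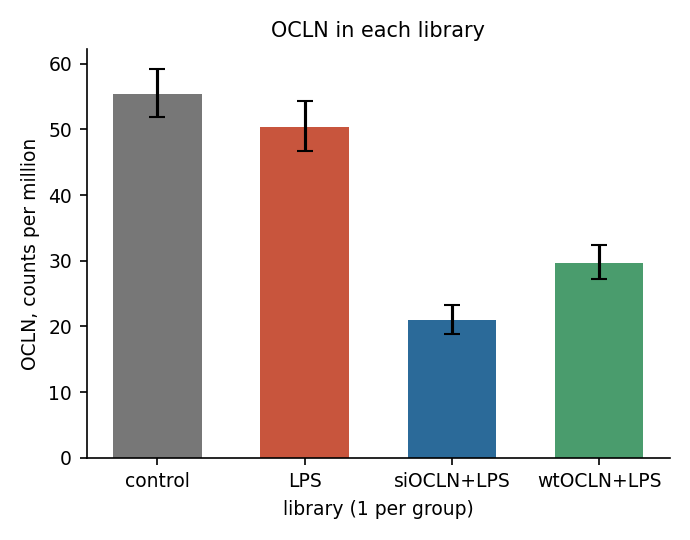
OCLN in CPM (vertical axis) in each of the 4 libraries (bars), with exact 95% Poisson intervals that cover counting error only. The siOCLN+LPS library, at 21.0 CPM, and the library labelled wtOCLN+LPS, at 29.7 CPM, both lie below LPS at 50.4 CPM and control at 55.4 CPM.

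The comparison of LPS with control shows the acute response of cells with no transfection in their labels. Secreted inflammatory factors were among the genes with the highest ratios. CXCL8, the neutrophil chemokine IL-8, was at 24.5 CPM in control and 1657 CPM in LPS, 67.5-fold higher (61.1 to 74.8). The pattern recognition protein PTX3 was 71.4-fold higher (59.4 to 86.4), the granulocyte growth factor CSF3 63.7-fold (51.4 to 80.0), the monocyte chemokine CCL2 75.5-fold (54.6 to 108), and CCL20 52.1-fold (43.6 to 62.7). CXCL1, IL6 and the epithelial transcription factor ELF3 were 42.1-, 28.1- and 43.3-fold higher. CSF2 was 91.4-fold higher on 9 counts in control and 718 in LPS (47.9 to 201). IL1B rested on 3 counts in control and 338 in LPS, a ratio of 129 (43.8 to 629).

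Of 13551 genes tested, 217 were at least 2-fold higher in LPS than in control and 28 at least 2-fold lower. Readthrough symbols made up 12 of the 217 and 9 of the 28, and these are uncertain. Of 26 measured cytokines and chemokines, 19 were at least 2-fold higher and 7 lay within 2-fold (list median log2 ratio 2.60, percentile 100). Of 38 NF-kB feedback and target genes, 30 were at least 2-fold higher (median 1.91, percentile 100). Among them were the NF-kB inhibitor TNFAIP3, 20.2-fold higher (18.9 to 21.5), and NFKBIZ, 16.8-fold higher. Immediate early genes stood above random lists (median 0.25), with 3 of 42 past 2-fold: KLF4, EREG and DUSP6 at log2 ratios of 1.53, 1.25 and 1.03. Proteases and their inhibitors had 6 of 32 members past 2-fold, including the stromelysin MMP3 (log2 ratio 3.99), SERPINB2 (2.64) and SERPINE2 (1.57). YAP/TAZ targets (median 0.11) had 4 of 29, led by EDN1 (2.26) and NUAK2 (2.09). The LPS sensing list had a median of 0.01, above random lists at -0.10, with 2 of 27 members past 2-fold: TLR2 (1.51) and the negative regulator IRAK3 (1.15). Airway secretory genes had 3 of 11 past 2-fold, PI3, LCN2 and MUC5AC, with a median of 0.67 that no longer stood apart without the filter on low values.

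Tight junction genes as a list did not stand apart in LPS (median -0.09, percentile 45.9; above 0 under median ratio and TMM scaling). CLDN1, a barrier claudin, was the exception at 6.39-fold higher (5.97 to 6.85), and the other 36 measured members lay within 2-fold. Interferon-stimulated genes did not stand apart either (median -0.12, percentile 34.5), with all 42 within 2-fold and DDX58, the RNA sensor RIG-I, highest at a log2 ratio of 0.93. The lowest genes included DOK7 (log2 ratio -1.32), IER5L (-1.22), FAM43A (-1.17), STAC2 (-1.11) and VGF (-1.06). Among 31 lists tried, 17 stood apart where chance gives 1.55, although several medians were small: cell cycle genes stood below at a median of -0.11, but not against random lists drawn without matching on expression. Fibroblast (median 0.12) and alveolar epithelial markers (0.13) also stood above, calls lost without the filter and with the mean. The ribosomal protein gene RPL21 had 0 counts in control and 247 in LPS, a difference not read as biology because it has many near-identical processed copies. At a 1.5-fold threshold 467 genes were higher and 379 lower, and at 3-fold 91 and 3. With a pseudocount of 5 the counts were 135 and 1, and with a pseudocount of 0.1 the number lower was 188.

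**Figure D2:**
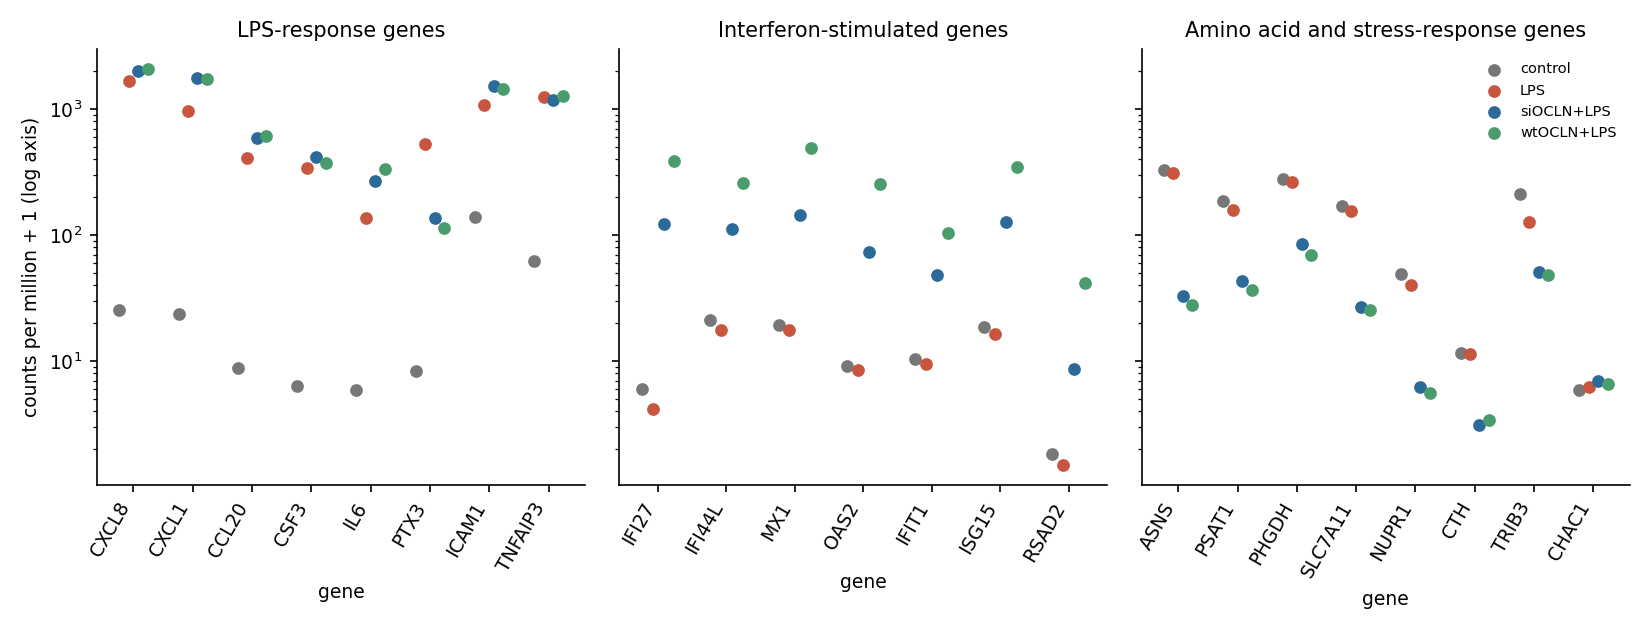
CPM plus 1 (log axis) of genes in 3 groups, 1 point per library, genes chosen after their values were seen. LPS-response genes differ between control and the 3 libraries given LPS, interferon-stimulated genes are higher in siOCLN+LPS and higher still in the library labelled wtOCLN+LPS (MX1 at 16.7, 144 and 488 CPM in LPS, siOCLN+LPS and the library labelled wtOCLN+LPS), and ASNS and PSAT1 are lower in both transfected libraries.

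The siOCLN+LPS library against LPS addresses what occludin siRNA did to cells under LPS, with the limit that transfection itself was not separated from the siRNA. Interferon-stimulated genes were the group farthest above the LPS library: 28 of 45 were at least 2-fold higher and none lower (median 1.31, percentile 100). IFI27 was 38.1-fold higher (28.3 to 52.6), IFI6 10.9-fold (9.81 to 12.1), the RNA-activated synthetase OAS2 9.58-fold (7.83 to 11.8) and the antiviral GTPase MX1 8.62-fold (7.53 to 9.91). Stress-response genes lay on the other side. In the list of unfolded protein and integrated stress response genes, 13 of 41 were at least 2-fold lower and 1 higher (median -0.59, percentile below 0.01). With the length and GC trend removed the median was -0.405, still below random lists. ASNS, asparagine synthetase, was at 312 CPM in LPS and 31.9 CPM in siOCLN+LPS, 9.77-fold lower (8.94 to 10.7), NUPR1 was 7.51-fold lower, the cystine transporter SLC7A11 5.92-fold lower and the serine synthesis enzyme PSAT1 3.73-fold lower.

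Of 13505 genes tested, 449 were at least 2-fold higher in siOCLN+LPS than in LPS and 530 at least 2-fold lower. Other genes far above LPS were ADGRF5 (39.7-fold, 22.0 to 79.9), IGFL1 (15.6-fold), CLIC5 (16.2-fold), GUCY1A2 (15.7-fold), the matrix protein NPNT (14.2-fold) and ATOH8 (9.24-fold). Epithelial genes stood above random lists (median 0.32), with 7 of 25 at least 2-fold higher and 1 lower. The keratin KRT19 was 6.74-fold higher, TP63, a basal cell transcription factor, 4.14-fold and KRT8 2.63-fold. YAP/TAZ targets ANKRD1 and CTGF were 6.03- and 2.66-fold higher (list median 0.19, 4 of 29 past 2-fold). Nuclear-encoded respiratory chain genes had a median of 0.39 over 72 members, and metallothioneins one of 0.74 with MT1X 2.77-fold higher and SLC30A1, a zinc exporter, 4.01-fold lower. Markers of some other cell types moved with these groups. The 7 tested fibroblast markers had a median of 0.48 and 7 alveolar epithelial markers one of 0.65, both above random lists. Past 2-fold higher were 1 fibroblast and 2 alveolar markers, and the alveolar call was lost at CPM 5 and without a filter. The 7 tested ciliated airway markers did not stand apart (-0.07). Cell cycle genes stood below (median -0.33), with E2F2, CCND1 and CDCA8 the 3 of 50 past 2-fold lower, while replication-dependent histone genes, many of which are near-identical copies, stood above (median 0.38), with 4 of 36 at least 2-fold higher and none lower. With the length and GC trend removed, these medians were -0.17 and 0.16.

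Inflammatory genes did not move one way in siOCLN+LPS. Cytokines and chemokines stood above random lists (median 0.25), with CCL2 5.45-fold higher (5.22 to 5.69) and the interferon-induced chemokine CXCL10 17.2-fold higher on 6 and 130 counts (7.69 to 47.7). NF-kB targets did not stand apart (median 0.05), with TNFAIP2 2.30-fold and IRF1 2.23-fold higher and PTX3 3.87-fold lower. TNFAIP6, a hyaluronan-binding protein, was 15.1-fold lower, the hyaluronan receptor CD44 9.96-fold lower (8.20 to 12.2), TNFSF14 7.51-fold lower and SERPINB2 17.6-fold lower (9.59 to 36.1). HSPA6, an inducible heat shock gene, had 187 counts in LPS and 1 in siOCLN+LPS, a ratio of 0.00424 (0.000107 to 0.0239). Immediate early genes stood below random lists matched on expression (median -0.25) but not below unmatched ones. The p53 targets stood below at a median of -0.31, a call lost with the mean, with unmatched lists and with the length and GC trend removed (percentile 12.2). Among tight junction genes (median -0.09, percentile 61.1; above 0 under the other scalings), MARVELD2, the tricellulin gene, was 4.08-fold lower, CLDN12 2.97-fold lower and CLDN11 3.06-fold higher. FAM133DP, at 266 counts in LPS and 0 in siOCLN+LPS, shares reads with related copies and is uncertain.

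Among the 30 lists tried here, 16 stood apart where chance gives 1.5. The split of genes past 2-fold depended on scaling: 45.9% were higher with library totals, 60.8% with median ratio scaling, 56.7% with upper quartile scaling and 61.5% with TMM. The median log2 ratio of all tested genes was -0.13 with library totals and 0.01 with TMM, and list medians are read against random lists that carry the same shift. With a pseudocount of 5 the counts were 226 higher and 189 lower, with a pseudocount of 0.1 the number lower was 932, and at 3-fold they were 123 and 105.

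The library labelled wtOCLN+LPS against LPS was meant to address added occludin, but OCLN was not higher in it. Interferon-stimulated genes were again farthest above the LPS library and by larger ratios: 40 of 45 were at least 2-fold higher and none lower (median 2.27, percentile 100). IFI27 was 123-fold higher (91.3 to 169), OAS2 33.9-fold (27.9 to 41.5), MX1 29.2-fold (25.6 to 33.4), IFI6 25.7-fold (23.2 to 28.5) and the ubiquitin-like modifier ISG15 22.4-fold (19.6 to 25.9). RSAD2 was 80.7-fold higher on 7 and 713 counts (39.0 to 201). The stress-response list had the same side as in siOCLN+LPS, with 9 of 41 at least 2-fold lower and 1 higher (median -0.59). With the length and GC trend removed its median was -0.35, still below random lists. ASNS was 11.7-fold lower (10.6 to 12.9), NUPR1 8.55-fold, SLC7A11 6.27-fold and PSAT1 4.46-fold lower.

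Of 13493 genes tested, 448 were at least 2-fold higher in the library labelled wtOCLN+LPS than in LPS and 498 at least 2-fold lower. ADGRF5 was 35.7-fold higher (19.8 to 71.9). Epithelial genes had a median of 0.47, with 5 of 25 at least 2-fold higher, among them TP63 (7.15-fold), KRT19 (4.97-fold), KRT8 (2.47-fold) and CDH1, E-cadherin (2.46-fold). ANKRD1 was 9.61-fold and CTGF 2.78-fold higher. Hypoxia and glycolysis genes had a median of 0.29 with 7 of 42 at least 2-fold higher, including CA9 (8.08-fold on low counts, 4.75 to 14.8) and DDIT4 (3.15-fold). Replication-dependent histone genes (median 0.45, or 0.32 with the length and GC trend removed), respiratory chain genes (0.29) and metallothioneins (0.79) stood above. So did 7 fibroblast markers (0.61) and 7 alveolar epithelial markers (0.65), while 7 ciliated airway markers did not stand apart (-0.13). Cell cycle genes stood below (-0.41, or -0.22 with that trend removed), with AURKA and E2F2 2.28- and 2.22-fold lower.

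CCL2 was 5.31-fold and IL6 2.46-fold higher in the library labelled wtOCLN+LPS than in LPS, and CXCL10 25.6-fold higher on 6 and 194 counts (11.6 to 70.7). The LPS sensing list did not stand apart (median -0.27, percentile 10.3), with 8 members above 0 and 19 below. Its LPS co-receptor CD14 was 3.80-fold and its adaptor MYD88 2.64-fold higher, TAB3 had a log2 ratio of -0.87, and TICAM2, at 23 and 0 counts, overlaps a readthrough gene and is uncertain. TNFAIP6 was 11.9-fold, CD44 9.18-fold, MMP3 9.92-fold, TNFSF14 7.94-fold and PTX3 4.64-fold lower, and HSPA6 had 187 counts in LPS and 0 there. Tight junction genes did not stand apart (median -0.06, percentile 80.0; above 0 under the other scalings), with MARVELD2 2.86-fold lower and CLDN11 3.93-fold higher. Among 30 lists, 15 stood apart where chance gives 1.5. Mesenchymal transition genes stood above (median 0.15), as epithelial genes did. Reference genes also stood above (median 0.16, percentile 98.0), a call lost with the mean and with the length and GC trend removed. In siOCLN+LPS against LPS the reference list lay at percentile 97.3. Standing apart therefore does not by itself mark a regulated pathway. Genes past 2-fold were 47.4% higher with library totals and 64.7%, 59.3% and 64.9% higher with median ratio, upper quartile and TMM scaling, and the median over all tested genes was -0.15 with library totals. With a pseudocount of 5 the counts were 254 and 173, with a pseudocount of 0.1 the number lower was 925, and at 3-fold they were 144 and 92.

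Of 979 genes at least 2-fold apart from LPS in siOCLN+LPS and 946 in the library labelled wtOCLN+LPS, 706 were shared in the same direction, 346 higher and 360 lower. With median ratio, upper quartile and TMM scaling, 483, 429 and 485 were higher in both and 247, 274 and 245 lower. The other 273 and 240 were apart in 1 library alone, and 0 were higher in one and lower in the other. Independent lists of these sizes would share 14.3 and 19.7 genes. Because both comparisons use the LPS library, unchanged libraries were simulated, and they shared 0.05 higher genes and none lower at a coefficient of variation of 0.0467, or 15.1 and 5.70 at 0.2. The simulation leaves out effects and the independent lists leave out the shared library, so neither excess measures a shared effect, and with 1 LPS library part of the excess may come from it. Across 13417 genes, which are not independent replicates, the ratios had a correlation of 0.93, against 0.55 and 0.51 in the simulated libraries, and a covariance of 0.30, against 0.01 and 0.08.

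**Figure D3:**
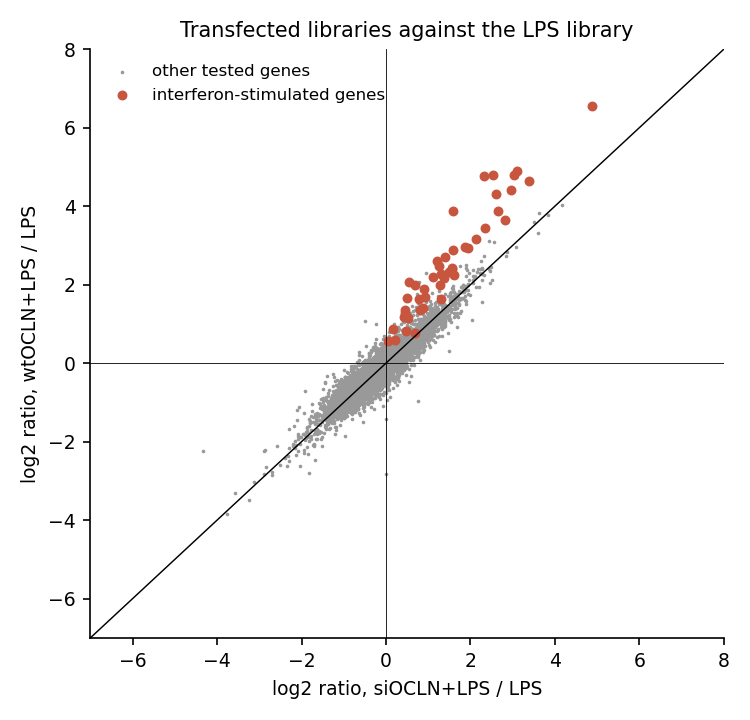
Log2 ratio of siOCLN+LPS to LPS (horizontal axis) against log2 ratio of the library labelled wtOCLN+LPS to LPS (vertical axis), 1 point per tested gene, with the line of equal ratios. Most genes follow the line, and interferon-stimulated genes (red) lie above it, with IFI27 highest at 4.87 and 6.55.

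The direct comparison of siOCLN+LPS with the library labelled wtOCLN+LPS shares no library with LPS against control, and both libraries were transfected. They were transfected differently, with siRNA or with wild-type occludin, so an effect of occludin is not separated from the kind of transfection. Interferon-stimulated genes were the list farthest from random lists: all 45 measured members were lower in siOCLN+LPS, 21 of them at least 2-fold (median -0.98, percentile below 0.01). MX2 was at 41.7 CPM in the library labelled wtOCLN+LPS and 6.87 CPM in siOCLN+LPS, 6.07-fold lower. CMPK2 was 6.23-fold lower (4.61 to 8.58), RSAD2 5.27-fold (4.38 to 6.39) and OAS2 3.54-fold (3.32 to 3.77). MX1, XAF1 and IFI27 were 3.38-, 3.34- and 3.22-fold lower. Of 13109 genes tested, 10 were at least 2-fold higher in siOCLN+LPS and 38 at least 2-fold lower, and 21 of the 38 belonged to the interferon list. Without that list 17 were lower.

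Outside the interferon list, 17 genes were lower and 10 higher, and the medians of the other lists described were small. Of these 17 genes, 5 had readthrough symbols and are uncertain. FAM133DP, at 0 CPM in siOCLN+LPS and 3.26 CPM in the library labelled wtOCLN+LPS, shares reads with related copies and is uncertain too. The list was fixed beforehand, so a gene outside it may still respond to interferon. Cytokines and chemokines (median -0.03) and NF-kB targets (0.02) did not stand apart, although the cytokine list stood below at CPM 5 or more (-0.05) and with the length and GC trend removed (-0.08), and none of their 28 and 38 members lay 2-fold apart. The immediate early list (median -0.11, KLF2 at a log2 ratio of -0.91), the YAP/TAZ list (-0.07, NT5E at -0.70), heat shock genes (-0.09), hypoxia and glycolysis genes (-0.06) and stress-response genes (-0.07) stood below random lists. Respiratory chain (0.11) and ribosomal protein genes (0.12) stood above. In these 7 lists no member lay 2-fold apart. Cholesterol synthesis genes stood below at a median of -0.03, a call lost with the mean, with unmatched lists and with the trend removed, and the heat shock call was lost with the mean. Of 30 lists, 9 stood apart where chance gives 1.5. Of the 10 genes higher in siOCLN+LPS, 6 had readthrough symbols, such as TMEM256-PLSCR3 with 107 counts against 0 and C7orf55-LUC7L2 (2.44-fold). SCHIP1 (4.57-fold), PLA2G4B (2.37-fold) and TICAM2 (1.66 CPM against 0) overlap readthrough genes. The readthrough symbols JMJD7-PLA2G4B and TMED7-TICAM2 went the other way, at 0.744 CPM against 4.11 and 3.83 CPM against 9.20. All of these depend on how overlapping reads were assigned and are uncertain. With readthrough symbols left out 4 genes were higher, SCHIP1, PLA2G4B and TICAM2 among them. With a pseudocount of 0.1 the counts were 79 and 82, and with a pseudocount of 5 they were 1 and 21.

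The last comparison followed the genes that differed between LPS and control. Of the 217 genes higher in LPS than in control, 138 were at least 2-fold above control in siOCLN+LPS (63.6%, exact binomial interval 56.8 to 70.0) and 126 in the library labelled wtOCLN+LPS (58.1%, 51.2 to 64.7). These shares are raised by the choice of the genes against the same control library, by an amount that was not measured. CXCL8, chosen after its values were seen, stood at 2000 and 2075 CPM there, against 1657 CPM in LPS. Against the LPS library the median log2 ratio of the 217 genes was -0.19 in siOCLN+LPS and -0.29 in the library labelled wtOCLN+LPS. With median ratio scaling, and also with upper quartile scaling, these values were -0.09 and -0.18. Some fall back is produced by choosing genes for a high LPS value, and simulated unchanged libraries gave -0.02 and -0.20 at the smaller and larger spread. With library totals the observed medians also carry a shift of all genes (matched random lists -0.09 and -0.12). The simulated libraries lack this shift, so the values are not like for like. Both medians of the LPS-raised genes stood below random lists, but not with a pseudocount of 5 or with the genes chosen at 3-fold, and the siOCLN+LPS call was also lost at CPM 5 or more. Of the 28 genes lower in LPS, 9 had readthrough symbols and are uncertain, and the medians that follow were not recomputed without them. Of all 28, 21 and 22 passed the filter and had medians of 0.71 and 0.87. Without the filter, which favours genes high in the transfected library, the medians over all 28 were 0.37 in siOCLN+LPS and 0.50 in the library labelled wtOCLN+LPS. Simulated unchanged libraries, also without it, gave 0.13 at the smaller spread and 0.41 at the larger, so the siOCLN+LPS value lay below the latter. These observed values also carry the shift of all genes, which the simulated ones lack. With the filter kept and genes chosen at 1.5-fold, the medians were 0.14 and 0.20, in place of 0.71 and 0.87.

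Between the transfected libraries, 130 of 203 tested LPS-raised genes were higher in siOCLN+LPS than in the library labelled wtOCLN+LPS (64.0%, exact binomial interval 57.0 to 70.6, genes not being independent), so 73 of 203 were higher in the latter. With library totals, matched random lists also leaned this way (median 0.02), so 50% is not the value to set this share against. The share higher in siOCLN+LPS was 57.6% with median ratio scaling and 61.0% with upper quartile scaling. The median log2 ratio was 0.05 (percentile 99.3), and 2 of the 203 genes lay at least 2-fold apart. With the LPS genes chosen at 1.5-fold or 3-fold, the medians were 0.03 in both cases and no longer stood apart. For the LPS-lowered genes the median was 0.05 (percentile 65.4), with a negative sign under median ratio and TMM scaling and at CPM 5 or more (-0.08).

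**Figure D4:**
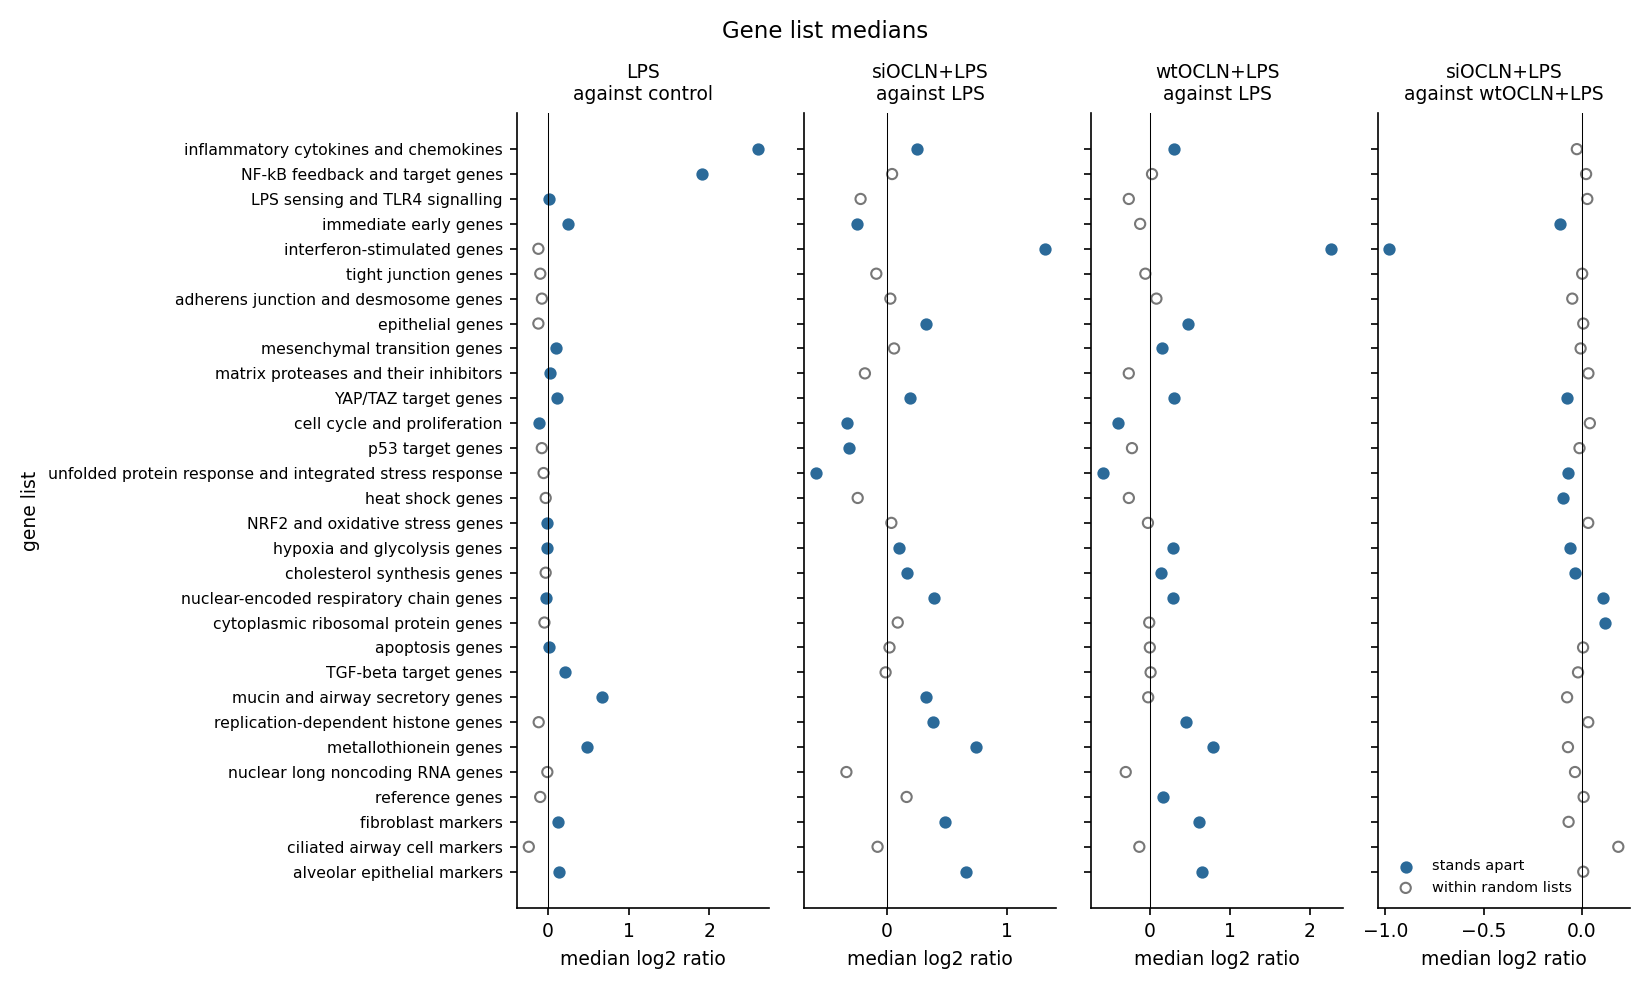
Median log2 ratio (horizontal axes, which differ in range) of each gene list in the 4 comparisons, 1 point per list. Filled points stand apart from random lists matched on expression and open points do not; cytokines at 2.60 and NF-kB targets at 1.91 lead LPS against control, and interferon-stimulated genes at 1.31 and 2.27 lead the transfected libraries against LPS.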

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

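All alternatives marked as added in the methods (TMM, the control library as reference, length and GC trend removed, interferon list left out, readthrough symbols left out) were chosen after seeing the data; the others were fixed beforehand. Equal library totals are what CPM already gives and no symbol was duplicated, so these settings move nothing and say nothing about stability. Leaving out a library could not be run with 1 per group. No paired analysis was possible because each group has 1 library. Of the list medians recomputed, 1136 kept their call, 27 no longer stood apart, 37 newly did, and no list that stood apart moved to the other side of the median of its random lists. A list median equal to that of the random lists, at 0, was counted as no longer apart and not as a change of side, a rule set after such values were seen; it concerned the alveolar and fibroblast markers and the airway secretory genes in LPS against control and the airway secretory genes in siOCLN+LPS against LPS, all without the filter. The number of lists standing apart stayed within 1.5 times the main number in all 40 recomputations. Of the list calls, 9 of 17 for LPS against control, 10 of 16 for siOCLN+LPS against LPS, 14 of 15 for the library labelled wtOCLN+LPS against LPS and 7 of 9 between the transfected libraries held in every alternative run. The OCLN fold of the library labelled wtOCLN+LPS against LPS was 0.661 with TMM, just past its counting interval, and the other 11 recomputed OCLN folds lay within theirs. Counts of genes moved with the threshold and pseudocount, by construction: a threshold of 1.5-fold gave 467 higher and 379 lower for LPS against control, 1227 and 2061 for siOCLN+LPS against LPS, 1159 and 2036 for the library labelled wtOCLN+LPS against LPS, 99 and 156 for siOCLN+LPS against the library labelled wtOCLN+LPS, and 946 higher and 1533 lower in both transfected libraries. The 3-fold threshold gave 91 and 3, 123 and 105, 144 and 92, 2 and 8, and 98 and 73. A pseudocount of 5 gave 135 and 1, 226 and 189, 254 and 173, 1 and 21, and 194 and 140. A pseudocount of 0.1 gave 188, 932 and 925 lower in the first 3 comparisons, 79 higher and 82 lower between the transfected libraries, and 681 lower in both. The filter at CPM 5 gave 13 lower for LPS against control and 4 higher between the transfected libraries. Leaving out readthrough symbols gave 4 higher and leaving out the interferon list 17 lower between them, and removing the length and GC trend gave 18 lower for LPS against control. The median of LPS-raised genes in siOCLN+LPS against LPS no longer stood apart with the CPM 5 filter (-0.0873), a pseudocount of 5 (-0.0711) and a 3-fold threshold (-0.0733). In the library labelled wtOCLN+LPS against LPS it no longer stood apart with a pseudocount of 5 (-0.0794), and with a 3-fold threshold (-0.0924) it lay on the other side of the random median; the cause was not tested. Between the transfected libraries it no longer stood apart at 1.5-fold (0.0275) and 3-fold (0.0332). The share of LPS-lowered genes higher in siOCLN+LPS than LPS was 85.7% with median ratio and with TMM scaling, and 93.3% for the library labelled wtOCLN+LPS. The share of LPS-raised genes higher was 45.9% with a pseudocount of 5 and 45.1% at 3-fold in the library labelled wtOCLN+LPS against LPS, and 55.0% at 1.5-fold between the transfected libraries. Depth limits genes near 1 CPM, where 1 CPM is 13.9 to 17.5 counts.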

Other observations

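The explanations weighed in this part were chosen for testing after seeing the data, with TMM scaling, the control library as reference and the removal of the length and GC trend. The gene lists, the OCLN folds, the medians of LPS-raised genes and the median ratio and upper quartile scalings that they draw on were fixed beforehand. The genes in this paragraph were chosen after their values were seen. Of 22 interferon genes, IFNE had 127 counts in control, 105 in LPS, 94 in siOCLN+LPS and 55 in the library labelled wtOCLN+LPS, and none of the others had more than 7 counts in any of the 4 libraries. IFNL1 had 7 counts in the library labelled wtOCLN+LPS, IFNL2 had 2 and IFNB1 had 1 there, and these 3 had 0 in the other libraries. The type I receptor subunit IFNAR2 was at 24.1 CPM in control, 37.6 in LPS, 57.4 in siOCLN+LPS and 57.0 in the library labelled wtOCLN+LPS. IRF9 was at 29.3, 24.3, 47.3 and 80.5 CPM in that order. The RNA sensor IFIH1 was at 35.7, 30.4, 52.7 and 97.1 CPM, while the endosomal RNA receptor TLR3 was at 20.2, 20.2, 11.2 and 16.6 CPM.

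The following LPS-raised genes, also chosen after their values were seen, differed in how they stood in the transfected libraries. TNFAIP6 was at 2.39 CPM in control, 51.8 in LPS, 3.43 in siOCLN+LPS and 4.34 in the library labelled wtOCLN+LPS. TNFSF14 was at 4.72, 40.4, 5.38 and 5.09 CPM, SERPINB2 at 0.944, 11.1, 0.629 and 1.54 CPM, and MMP3 at 0.315, 19.8, 4.92 and 2.00 CPM. CCL20 was at 7.80, 406, 590 and 606 CPM and CXCL1 at 22.8, 962, 1758 and 1721 CPM. CD44 was at 31.8 CPM in control and 6.58 and 7.14 CPM in the transfected libraries, below control as well as below LPS.

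OCLN was lower in the library labelled wtOCLN+LPS than in the LPS library. Scaling between libraries is argued against, since the highest fold over 4 scalings was 0.661. A transfected construct outside the counted reads, for example a coding sequence that differs from the annotated transcript, may leave only endogenous transcript visible in the 519 OCLN counts, and this cannot be told apart from a construct that was not expressed. Either would account for OCLN not lying above the LPS library. Neither would by itself account for OCLN lying below it, at a fold of 0.588 (0.524 to 0.660). What lowered OCLN in this library was not tested. A swap of the labels of the transfected libraries cannot be told apart either. Neither OCLN fold exceeded 1 (upper counting bound of the higher, 0.660), so no library showed the raised OCLN that would mark the wild-type occludin transfection.

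Interferon-stimulated genes were higher in both transfected libraries than in the LPS library, and higher in the library labelled wtOCLN+LPS than in siOCLN+LPS. Scaling between libraries is argued against, since the lowest list median over 4 scalings and both libraries was 1.31. Leukocytes in the culture are argued against by 30 marker genes, whose median was 0 CPM in both transfected libraries, with PTPRC at 0 counts and 2 markers at 1 CPM or more: CD68, at 16.6 CPM in LPS and 4.98 and 7.49 CPM in the transfected libraries, and CORO1A, at 2.96, 8.24 and 7.66 CPM. Stronger LPS signalling cannot be told apart, because its rows go both ways. LPS-raised genes had medians of -0.19 and -0.29 against LPS, where matched random lists had -0.09 and -0.12. The choice of genes alone gave -0.02 to -0.20 in simulated unchanged libraries, which lack that shift of all genes. The cytokine and chemokine list, which holds the interferon-induced CXCL10, stood above random lists in both (0.25 and 0.29). The NF-kB list did not stand apart in either (0.05 and 0.02). The interferon list did not stand apart in LPS against control (median -0.12). A response to transfected nucleic acid is a candidate explanation with the siOCLN+LPS median of 1.31, but it cannot be told apart from an effect of occludin or of a separate culture, since no library is stated to be mock transfected. For the difference between the transfected libraries, occludin cannot be told apart from the kind of transfection, siRNA or wild-type occludin.

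Both transfected libraries differed alike from the LPS library. A deviation of the LPS library alone is argued against, because 475 of the 706 genes called in both (67.3%) were also at least 2-fold from control in the same direction in both. A trend with transcript length and GC content is argued against as the whole cause, since 567 of the 706 (80.3%) kept their call after its removal. Length and GC values were known for 94.6% of the genes called in siOCLN+LPS and 94.7% in the library labelled wtOCLN+LPS. The other called genes kept their ratios, and so their calls, by construction. Removal also centres the ratios, so the loss among the lower genes, of which 236 of 360 kept their call, is not put down to the trend: TMM scaling alone gave 245 lower in both. The transfection procedure, the siRNA or plasmid, and a separate culture batch could each account for the 706 genes and cannot be told apart in this design.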
